A study of Mus musculus with 7 samples.

How the data were processed

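Messenger RNA was measured by sequencing in 7 libraries of sorted mouse Tregs, 3 from SDLN and 4 from skin. Per the labels, sorted cells were pelleted and flash frozen, RNA was purified on columns, and cDNA was made with the SMARTer Ultra Low Input kit. The deposited values are raw read counts per gene symbol that the authors made with HTSeq 0.6.1, with no normalization; the submitters' processing notes also name CASAVA 1.8.2, TopHat2 2.0.12, Bowtie2 2.1.0.0, SAMtools 0.1.19.0 and the mouse genome build mm10. The gene annotation, strand setting and filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned to one of them, and the gates of the sort and the number of animals per library are not given either; libraries were treated as independent. The table held 24084 gene symbols and 5 summary lines; 27 symbols had been turned into dates and were kept under those names, and no mitochondrial gene was in it, so the mitochondrial share was not computed. Of all counts in the table, 61.2% to 70.4% stood on the summary line for alignments to several places and 10.0% to 17.1% on that for reads outside annotated genes. A read with several alignments may have been counted more than once, so these are not shares of reads. All 7 columns were assigned to their libraries by their titles. Coordinates of named genes are those of the GENCODE annotation of the same build, matched by symbol, and each gene given with a position is protein-coding there.

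Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3 with its minimum count of 10, which left 11376. Libraries were scaled by TMM, and skin was compared with SDLN by edgeR's quasi-likelihood test with robust fitting and tissue as the sole term, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. CPM were computed on the TMM-scaled library sizes, and SDs are over libraries. A gene with no count in a whole group was given a bound on its fold from the mean CPM that 3 counts stand for in each library of that group; a gene with 1 to 3 counts in a group was given the ratio with a 95% counting interval. These intervals and floors cover counting error alone, and PCR copies are not independent molecules. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, with adjustment over the 26 lists that had at least 3 measured members, and beside it with an estimated correlation and with fry. Library measures were compared by exact permutation over the 35 splits of the 7 libraries, two-sided, with adjustment over the measures. The lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except for 2 added alternatives, a variance weight per group in limma-voom and the sex of the library as a covariate.

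Named genes are Foxp3, Il2ra and Jag1; the 8 genes higher and the 8 lower with the smallest adjusted p among those with a log2 fold change of at least 1 in size, a mean of at least 20 CPM, no overlap of the tissues, an established symbol and no place in a marker list; up to 2 called members with the smallest adjusted p of each pathway list, or its most abundant member; and the most abundant member of each list of other cell types. Some of these genes are not reported here. Sex-linked genes were read as a check of the animals' sex, which the labels do not give. The alternatives were RLE, upper-quartile or no scaling, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom with and without sample weights, fitting without robust estimation, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a test against a fold of 1.5 with glmTreat, an estimated correlation, and lists without shared members. The test was also run on simulated counts with 200 changed genes, 3 times per setting. With a spread per gene like that of all libraries it made 0 false calls and recovered 0%, 2.68% and 17.9% of genes changed 2-, 4- and 8-fold, and with each tissue's own spread 0 false calls and 0%, 2.04% and 12.6%. With the SDLN spread in both tissues, 6.59% of calls were false and recovery was 45.0%, 92.4% and 99.0%. In a simulation of 24 lists, none was called without a shift and a list shifted 4-fold was called. Genes were drawn independently there, so it cannot show how the list test fares with correlated genes.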

Results

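The series profiled messenger RNA of regulatory T cells (Tregs), the CD4 T cell lineage defined by the transcription factor Foxp3, sorted from the skin and from the skin-draining lymph nodes (SDLN) of mice aged 6 weeks, with the skin named as telogen, the resting phase of the hair cycle. The mice carried a Foxp3 reporter allele that links a green fluorescent protein and the diphtheria toxin receptor to Foxp3. There were 3 SDLN and 4 skin libraries, and the stated purpose was to compare the transcriptomes of Tregs from the 2 tissues. Total gene counts, rounded to 6 digits, were 14785800, 14132000 and 13123200 in SDLN 1 to 3 and 11991200, 12404400, 11009600 and 13921200 in skin 1 to 4, and a count of 3 corresponded to 0.204 to 0.276 CPM. Genes with at least 1 count numbered 13583 ± 231 (SD, n = 3) in SDLN and 10858.5 ± 1333 (SD, n = 4) in skin (exact permutation test, two-sided, p = 0.0571, Benjamini-Hochberg adjusted 0.309; the smallest p that the 35 splits allow is 0.0286). Malat1, a nuclear long noncoding RNA, had a share of the gene counts of 0.638 ± 0.428% (SD, n = 3) in SDLN and 1.90 ± 0.9996% (SD, n = 4) in skin (exact permutation p = 0.0857, adjusted 0.309). Correlations of log2 CPM across genes were 0.964 to 0.981 between SDLN libraries, 0.624 to 0.699 between skin libraries and 0.617 to 0.700 between the tissues, so skin libraries differed from each other about as much as they differed from SDLN. The median coefficient of variation per gene was 0.187 in SDLN and 0.7499 in skin. The Y-linked gene Ddx3y had 3877 counts in SDLN 3 and at most 2 in any other library, while Xist had 4 counts in SDLN 3 and 4653 to 11758 elsewhere. One tissue tag of skin 1 names the lymph node, whereas its title and source name skin. In a comparison built without skin 1, 1228 genes were called. Skin 1 lay nearer the skin mean than the SDLN mean for 72.4% of them. For skin 2, 3 and 4, each in a comparison built without it, this share was 83.6%, 68.3% and 77.9%. Skin 1 lay on the skin side of the SDLN mean for 85.3%, against 91.6%, 83.5% and 88.8% for skin 2, 3 and 4. Below, values are CPM as mean ± SD over n = 3 SDLN and n = 4 skin libraries unless stated, and fold changes are skin over SDLN.

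Skin Tregs had higher transcripts of effector and tissue Treg genes than SDLN Tregs (camera adjusted p = 2.03e-16, and adjusted p = 0.0443 with an estimated correlation). With the preset correlation, chemokine and homing receptors were also higher and genes of naive and recirculating T cells lower, but neither list passed with an estimated correlation (adjusted p = 0.0748 and 0.0605). Rora, a nuclear receptor of tissue lymphocytes (chromosome 9, 68653786 to 69388246), was 21.6-fold higher in skin, at 46.7 ± 6.76 CPM (SD, n = 3) in SDLN and 1007 ± 177.5 CPM (SD, n = 4) in skin (log2 fold change 4.43, SE 0.28, adjusted p = 0.00104). Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477273), was 339-fold higher, at 4.81 ± 1.11 against 1633 ± 799 CPM (log2 fold change 8.41, SE 0.61, adjusted p = 0.00127), and did not pass with limma-voom (adjusted p = 0.0617, the highest over all alternatives). S1pr1, the receptor that guides lymphocyte exit from lymphoid organs (chromosome 3, 115710433 to 115715072), was 15.1-fold lower, at 1018 ± 56.9 against 67.4 ± 34.8 CPM (log2 fold change -3.92, SE 0.39, adjusted p = 0.00377); its skin 1 value of 119 CPM stood apart from 45.2 to 54.8 CPM in the other skin libraries.

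Among the 3 genes named in advance, Jag1, a Notch ligand (chromosome 2, 137081456 to 137116644), rose, at 0.393 ± 0.209 CPM (SD, n = 3) in SDLN and 71.6 ± 27.9 CPM (SD, n = 4) in skin (log2 fold change 7.47, SE 0.86, adjusted p = 0.00563). Jag1 had 17 counts in all over the SDLN libraries, and it did not pass without SDLN 2 (adjusted p = 0.0542, and 3.63e-24 to 0.0598 over all alternatives). Foxp3 (chromosome X, 7573644 to 7595245) was at 89.0 ± 17.7 CPM (SD, n = 3) in SDLN and 169 ± 65.2 CPM (SD, n = 4) in skin, with no overlap between the libraries, and did not pass the test (log2 fold change 0.93, SE 0.38, adjusted p = 0.242). Il2ra, the interleukin-2 receptor alpha chain CD25 (chromosome 2, 11642807 to 11693193), was at 1662.5 ± 108 against 1367 ± 246 CPM and did not pass it either (log2 fold change -0.28, SE 0.21, adjusted p = 0.585).

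Besides Rora and Fos, the 8 genes that headed the ranking of genes higher in skin were Ahnak, N4bp1, Lmna, Fosl2, Gem and Myadm. Ties in adjusted p, here and among lower genes, were ordered by the larger log2 fold change in size. Nr4a1 tied with Fos in adjusted p and came after these genes by that rule. Ahnak, a very large scaffold protein (chromosome 19, 8989284 to 9076914), was at 163 ± 18.5 against 3378 ± 582 CPM (log2 fold change 4.37, SE 0.26, adjusted p = 0.00104). N4bp1, an inhibitor of NF-kappaB signalling and ubiquitin ligases (chromosome 8, 86808160 to 86885258), was at 46.0 ± 6.62 against 602 ± 72.4 CPM (log2 fold change 3.71, SE 0.26, adjusted p = 0.00124). Lmna, the nuclear lamina protein lamin A/C (chromosome 3, 88480147 to 88509956), was at 5.12 ± 0.507 against 780.1 ± 439 CPM (log2 fold change 7.25, SE 0.56, adjusted p = 0.00127), with 1429.6 CPM in skin 2 and 459.7 to 623 CPM in the other skin libraries. Fosl2, another AP-1 subunit (chromosome 5, 32135801 to 32157842), was at 2.82 ± 1.08 against 279 ± 80.8 CPM (log2 fold change 6.62, SE 0.49, adjusted p = 0.00127). Gem, a small GTPase of the RGK family (chromosome 4, 11704457 to 11714752), was at 9.80 ± 1.97 against 369 ± 107 CPM (log2 fold change 5.23, SE 0.41, adjusted p = 0.00127). Myadm, a membrane protein (chromosome 7, 3289080 to 3300442), was at 18.7 ± 2.32 against 426 ± 129 CPM (log2 fold change 4.51, SE 0.36, adjusted p = 0.00127).

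Besides S1pr1, the 8 genes that headed the ranking of genes lower in skin included Gpr18, Gimap4, Treml2, Ift80, Evl and Lef1. Gpr18, a G protein-coupled receptor of lymphocytes (chromosome 14, 121911253 to 121915781), had 231 ± 41.2 CPM in SDLN and 2 counts in all over the skin libraries, a ratio of 5574 with a 95% counting interval of 1543 to 46035 (adjusted p = 0.00104). Treml2, a receptor of the TREM-like family (chromosome 17, 48299498 to 48312533), had 139 ± 25.1 CPM in SDLN and no count in skin, which puts it at least 556.5-fold lower when 3 counts per skin library are taken as the floor (adjusted p = 0.00388). Gimap4, a GTPase of the immunity-associated family in lymphocytes (chromosome 6, 48684549 to 48692060), was at 2194 ± 492 against 92.5 ± 45.9 CPM (log2 fold change -4.57, SE 0.44, adjusted p = 0.00377). Ift80, a component of intraflagellar transport (chromosome 3, 68892499 to 69004570), was at 621 ± 126 against 67.1 ± 21.6 CPM (log2 fold change -3.21, SE 0.33, adjusted p = 0.00388). Evl, an actin regulator of the Ena/VASP family (chromosome 12, 108554720 to 108688516), was at 174 ± 8.71 against 10.3 ± 4.31 CPM (log2 fold change -4.08, SE 0.44, adjusted p = 0.00429). Lef1, a transcription factor of naive T cells (chromosome 3, 131110471 to 131224356), was at 470.1 ± 54.1 against 69.0 ± 24.8 CPM (log2 fold change -2.77, SE 0.32, adjusted p = 0.00617). With the replicate number as a block, on 6 or 7 libraries, Treml2 and Evl did not pass (adjusted p up to 0.0559 and 0.0563, the highest over all alternatives). Lef1 did not pass with the block on 6 libraries (adjusted p = 0.0553, the highest over all alternatives) but passed with the block on 7.

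**Figure D1:**
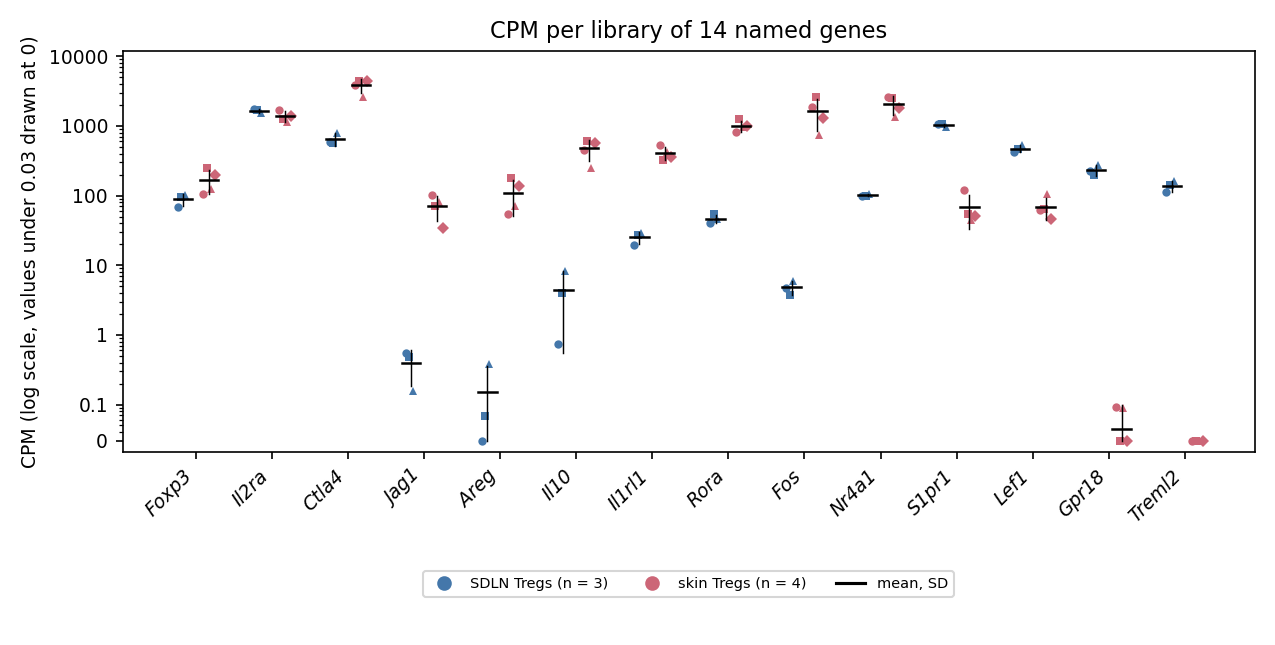
CPM of 14 genes (x axis) in each library (y axis, log scale, with values under 0.03 drawn at 0), SDLN in blue and skin in red, with 1 symbol per library; lines show the mean and SD over n = 3 SDLN and n = 4 skin libraries. Treml2 lies at 0 in all 4 skin libraries.

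Of 11376 genes tested with edgeR's quasi-likelihood test, 824 (7.24%) passed an adjusted p of 0.05, 373 of them higher in skin and 451 lower, and 370 and 447 of these differed by at least 2-fold. The 2 tissues' libraries did not overlap for any of the 824 genes. Over all tested genes 26.6% did not overlap. If all libraries were drawn alike, 5.71% would not overlap. That share does not hold here, since the median coefficient of variation was 0.187 in SDLN and 0.7499 in skin. Of the 451 lower genes, 269 had no count in any skin library, and 108 had counts in all 4. Tested genes with no skin count numbered 271 in all. Such genes pass the low-count filter through SDLN alone, so nearly all of them were called. The 269 had a median SDLN level of 2.82 CPM, against 170.6 CPM for the other lower genes. Skin libraries also had fewer genes detected, as given above. Of the 373 higher genes, 2 had no count in any SDLN library. The counts rest on the small SDLN group: without SDLN 1, 2 or 3 they were 39, 33 and 61 higher and 9, 10 and 15 lower, with the sex of the library as a covariate 62 and 16, and without skin 1 or skin 3 they were 582 and 448 higher and 646 and 822 lower. SDLN 3 was the sole male library, so the sex covariate acts much as leaving SDLN 3 out. Of the 46 named genes that passed the test, 31 failed it under at least 1 alternative, and the number of lower genes was 70 without the low-count filter and 99 among genes with a mean of at least 5 CPM.

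**Figure D2:**
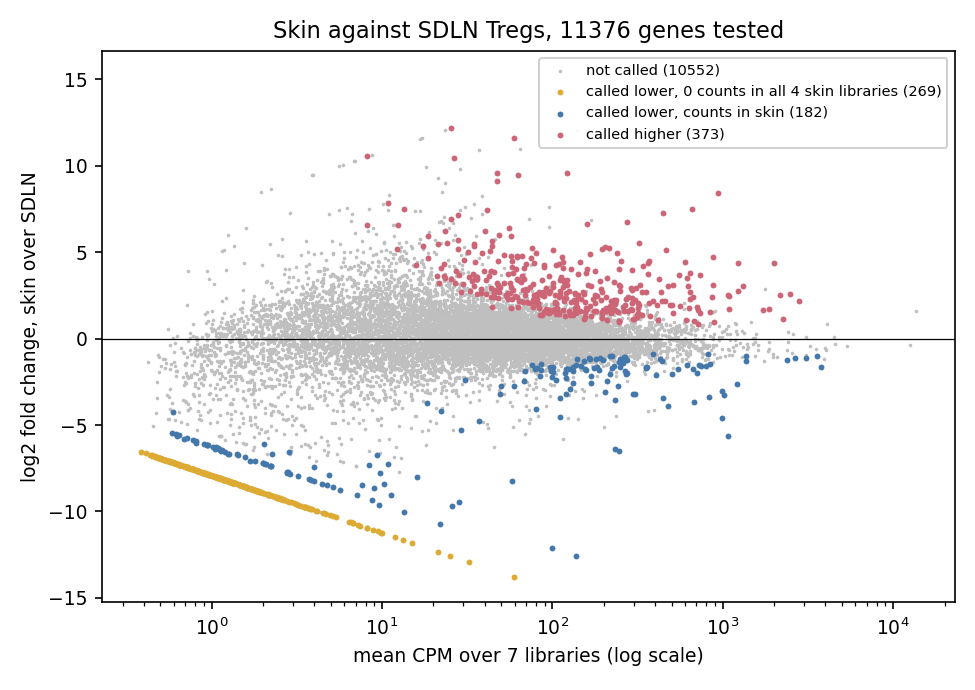
Fitted log2 fold change of each of the 11376 tested genes (y axis, skin over SDLN) against its mean expression over the 7 libraries (x axis, CPM, log scale). Red marks the 373 genes higher in skin at an adjusted p under 0.05, yellow the 269 lower genes with no skin count and blue the other lower genes. The fitted folds of the 269 lower genes with no skin count depend on the prior count and are not measured folds.

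Effector and tissue Treg genes were higher in skin as a group with the preset correlation (camera adjusted p = 2.03e-16) and passed also with an estimated one (adjusted p = 0.0443 with an estimated correlation). Of 21 measured effector genes, 16 rose, 0 fell and 5 did not pass, with 18 higher and 1 lower adjusted over the list alone. Effector genes that were lower numbered 0 in edgeR, 1 at an unadjusted p under 0.05, 1 with DESeq2 and 1 with limma-voom. No other of the 26 lists tested passed with an estimated correlation. Rora and Il1rl1, the interleukin-33 receptor, had the smallest adjusted p, with Il1rl1 at 25.4 ± 4.97 against 412 ± 91.8 CPM (log2 fold change 4.02, adjusted p = 0.00138). Effector genes that rose numbered 5, 3 and 10 without SDLN 1, 2 and 3. Effector genes that fell numbered 1 without skin 3. Macrophage and dendritic cell markers were higher too, summing to 22.9 against 569 CPM, with each skin library above each SDLN library, and genes detected were fewer in skin, at 10858.5 against 13583.

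Genes of the core Treg programme moved both ways. Of 20 measured core Treg genes, 4 rose, 4 fell and 12 did not pass, with 4 higher and 4 lower adjusted over the list alone. For core Treg genes the camera adjusted p was 0.123, and adjusted p = 0.539 with an estimated correlation. Ctla4, an inhibitory receptor, rose, at 651 ± 132 against 3819.8 ± 856 CPM (log2 fold change 2.55, adjusted p = 0.00501). Il10, an inhibitory cytokine, rose as well, at 4.36 ± 3.81 against 474 ± 163 CPM (log2 fold change 6.76, adjusted p = 0.00998). The transcription factor Ikzf2 (log2 fold change 1.15, adjusted p = 0.0385) and Itgb8, an integrin that activates TGF-beta (log2 fold change 2.49, adjusted p = 0.0354), were the other two that rose. The ectonucleotidase Nt5e (log2 fold change -1.17, adjusted p = 0.0394) and the folate receptor family member Izumo1r (log2 fold change -3.65, adjusted p = 0.0342) fell. So did the receptor Gpr83 (log2 fold change -6.48, adjusted p = 0.0388) and the co-receptor Nrp1 (log2 fold change -3.19, adjusted p = 0.0204). Core Treg genes that rose numbered 1, 0 and 2 without SDLN 1, 2 and 3. Core Treg genes that fell numbered 0 without any 1 SDLN library, 2 without skin 2 and 2 without skin 3. Core Treg genes passed the list test without skin 3 (adjusted p = 0.0365, and 0.0365 to 0.539 over all alternatives). Ctla4 did not pass without SDLN 1 or SDLN 2 (adjusted p 0.0519 to 0.0546, and 5.02e-16 to 0.0965 over all alternatives). Il10 did not pass without SDLN 2 (adjusted p = 0.0762, and 1.18e-20 to 0.0762 over all alternatives). Il10 had a log2 fold change of 7.62 without SDLN 3. Members named beside a count of 5 or fewer, here and for other lists, were chosen after their values were seen unless the rule for named genes took them.

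Genes of naive and recirculating T cells were lower as a group with the preset correlation (camera adjusted p = 2.46e-04) but did not pass with an estimated one (adjusted p = 0.0605 with an estimated correlation). Of 20 measured naive T cell genes, 1 rose, 5 fell and 14 did not pass, with 1 higher and 9 lower adjusted over the list alone. Beside S1pr1 and Lef1, the chemokine receptor Ccr7, which directs cells to lymph nodes, fell, at 929 ± 82.7 against 84.5 ± 48.9 CPM (log2 fold change -3.46, adjusted p = 0.0117). Tcf7, a transcription factor of naive T cells, fell as well, at 538 ± 38.3 against 6.38 ± 7.34 CPM (log2 fold change -6.39, adjusted p = 0.0380). Il7r, the interleukin-7 receptor alpha chain, was the 1 member that rose (log2 fold change 1.46, adjusted p = 0.0380). Naive T cell genes that rose numbered 0 without any 1 SDLN library. Naive T cell genes that fell numbered 3 without any 1 SDLN library. The lower number of genes detected in skin, 10858.5 against 13583, moved with this list. Chemokine and homing receptors were higher as a group with the preset correlation (camera adjusted p = 1.55e-06) but did not pass with an estimated one (adjusted p = 0.0748 with an estimated correlation). Of 21 measured homing receptors, 10 rose, 1 fell and 10 did not pass, with 12 higher and 2 lower adjusted over the list alone. Cxcr4, the receptor for Cxcl12, was at 4.83 ± 0.234 against 172 ± 71.6 CPM (log2 fold change 5.15, adjusted p = 0.00377). Itgae, the integrin chain CD103 that binds E-cadherin, was at 288 ± 30.2 against 1928.5 ± 616 CPM (log2 fold change 2.74, adjusted p = 0.00610). Cxcr5, which directs cells to B cell follicles, was the 1 member that fell (log2 fold change -5.31, adjusted p = 0.0260). Homing receptors that rose numbered 1, 1 and 4 without SDLN 1, 2 and 3. Homing receptors that fell numbered 0 without any 1 SDLN library and 2 without skin 4. Itgae did not pass without SDLN 1 or SDLN 2 (adjusted p 0.0519 to 0.0615, and 9.27e-15 to 0.0749 over all alternatives). Cxcr4 did not pass with limma-voom or with the replicate block on 6 libraries (adjusted p = 0.0586, the highest over all alternatives). Macrophage and dendritic cell markers summed to 22.9 ± 5.35 CPM (SD, n = 3) in SDLN and 569 ± 498 CPM (SD, n = 4) in skin (exact permutation p = 0.0857, adjusted 0.309).

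In the Notch pathway, Jag1 rose, with values given above. Of 18 measured Notch pathway genes, 1 rose, 1 fell and 16 did not pass, with 2 higher and 1 lower adjusted over the list alone. For Notch pathway genes the camera adjusted p was 0.662, and adjusted p = 0.689 with an estimated correlation. The Notch list had a median log2 fold change of -0.52, a mean of 0.25 and an upward test. Notch pathway genes that rose numbered 1, 0 and 1 without SDLN 1, 2 and 3 and 2 without skin 3. Notch pathway genes that fell numbered 0 without any 1 SDLN library. Among growth factor and repair ligands, Areg and Il10 rose and Lif fell. Of 12 measured growth factor ligands, 2 rose, 1 fell and 9 did not pass, with 2 higher and 1 lower adjusted over the list alone. For growth factor ligands the camera adjusted p was 0.00310, and adjusted p = 0.118 with an estimated correlation. Lif, a cytokine of the interleukin-6 family, had 4.61 ± 1.38 CPM in SDLN and 1 count in all over the skin libraries, a ratio of 226 with a 95% counting interval of 40.1 to 8965 (adjusted p = 0.0380). Areg, the epidermal growth factor receptor ligand amphiregulin, was at 0.152 ± 0.206 against 109 ± 58.3 CPM (log2 fold change 9.45, adjusted p = 0.00998). It had 6 counts in all over the SDLN libraries and 0 in SDLN 1. Its SDLN mean lay under the 0.204 to 0.276 CPM of 3 counts, so the size of its fold is uncertain. Without members shared with other lists the ligands did not pass the list test (adjusted p = 0.147, the highest over all alternatives). Growth factor ligands that rose numbered 2, 0 and 2 without SDLN 1, 2 and 3. Growth factor ligands that fell numbered 0 without any 1 SDLN library. Along with the ligands, macrophage and dendritic markers were higher, at 22.9 against 569 CPM in sum. Of the TNF receptor superfamily, Tnfrsf1b, the TNF receptor 2, rose, at 324 ± 48.2 against 1005 ± 287 CPM (log2 fold change 1.64, adjusted p = 0.0272). Tnfrsf10b, a receptor for the ligand TRAIL, rose too, at 4.99 ± 0.373 against 59.5 ± 26.0 CPM (log2 fold change 3.57, adjusted p = 0.0272). Tnfrsf25, the death receptor DR3, fell (log2 fold change -1.65, adjusted p = 0.0414). Of 13 measured TNF receptors, 2 rose, 1 fell and 10 did not pass, with 2 higher and 1 lower adjusted over the list alone. For TNF receptors the camera adjusted p was 0.315, and adjusted p = 0.539 with an estimated correlation. TNF receptors that rose numbered 0 without any 1 SDLN library. TNF receptors that fell numbered 0 without any 1 SDLN library, 0 without skin 2, 0 without skin 3 and 0 without skin 4. Jag1, Areg and Il10 did not pass without SDLN 2 (adjusted p 0.0542 to 0.0762, and 3.63e-24 to 0.0763 over all alternatives). Tnfrsf1b and Tnfrsf10b did not pass without any 1 SDLN library (adjusted p 0.133 to 0.176, and 6.01e-09 to 0.229 over all alternatives). The log2 fold change of Areg was 8.85 without SDLN 1 and 11.27 without SDLN 3.

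Genes tied to type 2 helper cells were higher as a group with the preset correlation (camera adjusted p = 2.46e-04) but did not pass with an estimated one (adjusted p = 0.0605 with an estimated correlation). Of 9 measured type 2 genes, 4 rose, 0 fell and 5 did not pass, with 5 higher and 1 lower adjusted over the list alone. Type 2 genes that were lower numbered 0 in edgeR, 1 at an unadjusted p under 0.05, 1 with DESeq2 and 1 with limma-voom. Without members shared with other lists the type 2 test turned downward (adjusted p = 0.915). The members past the test were Gata3, Il1rl1, Ccr3 and Areg. Ccr3, a receptor for eotaxins, was at 13.7 ± 1.22 against 141 ± 56.0 CPM (log2 fold change 3.36, adjusted p = 0.00998), and the transcription factor Gata3 at 104 ± 5.50 against 325 ± 118 CPM (log2 fold change 1.65, adjusted p = 0.0380). Type 2 genes that rose numbered 2, 1 and 2 without SDLN 1, 2 and 3. Of the type 17 list, Rora, the chemokine receptor Ccr6 (log2 fold change 1.96, adjusted p = 0.0304) and Stat3 rose. Of 6 measured type 17 genes, 3 rose, 0 fell and 3 did not pass, with 4 higher and 0 lower adjusted over the list alone. Type 17 genes that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. For type 17 genes the camera adjusted p was 3.75e-04, and adjusted p = 0.193 with an estimated correlation. Stat3, a transducer of interleukin-6 family signals, was at 158 ± 6.01 against 440.1 ± 40.3 CPM (log2 fold change 1.48, adjusted p = 0.0117). Type 17 genes that rose numbered 1 without any 1 SDLN library. Each called member but Stat3 also belongs to another list. Without shared members the type 17 list did not pass (adjusted p = 0.232, the highest over all alternatives). The macrophage and dendritic marker sum, at 22.9 against 569 CPM, moved with both lists. Of the type 1 list, Stat4, a transducer of interleukin-12 signals, fell, at 219 ± 27.0 against 45.02 ± 30.1 CPM (log2 fold change -2.28, adjusted p = 0.0380), with 89.6 CPM in skin 4 and 23.8 to 34.9 CPM in the other skin libraries. Of 11 measured type 1 genes, 1 rose, 1 fell and 9 did not pass, with 4 higher and 1 lower adjusted over the list alone. For type 1 genes the camera adjusted p was 0.0554, and adjusted p = 0.425 with an estimated correlation. Type 1 genes that rose numbered 0 without any 1 SDLN library, 2 without skin 1 and 2 without skin 3. Type 1 genes that fell numbered 0 without any 1 SDLN library, 0 without skin 1 and 0 without skin 2. Type 1 genes passed the list test without SDLN 3, skin 2 or skin 3 (adjusted p = 0.0389, 0.0269 and 0.0245, and 0.0245 to 0.425 over all alternatives). Ccr3 and Stat3 did not pass without any 1 SDLN library (adjusted p 0.0691 to 0.132, and 1.18e-12 to 0.188 over all alternatives). Stat4 did not pass without any 1 SDLN library or without skin 1 or without skin 2 (adjusted p 0.0510 to 0.176, and 2.83e-04 to 0.176 over all alternatives). The log2 fold change of Stat4 was -2.87 without skin 4.

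Interferon-stimulated genes were lower as a group with the preset correlation (camera adjusted p = 7.49e-06) but did not pass with an estimated one (adjusted p = 0.141 with an estimated correlation). Of 24 measured interferon-stimulated genes, 0 rose, 5 fell and 19 did not pass, with 0 higher and 5 lower adjusted over the list alone. Interferon-stimulated genes that were higher numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. Rtp4, a receptor transporter protein, fell, at 252 ± 56.4 against 42.5 ± 16.7 CPM (log2 fold change -2.57, adjusted p = 0.0145), as did Ifi35, at 312 ± 47.8 against 157 ± 22.4 CPM (log2 fold change -0.99, adjusted p = 0.0496). Oasl2 and Oasl1, of the oligoadenylate synthetase-like family, had no skin count, and nearly all tested genes with no skin count were called. Oasl2, with 58.7 ± 11.3 CPM in SDLN, was at least 235-fold lower (adjusted p = 0.0116). Oasl1, with 20.6 ± 4.63 CPM in SDLN, was at least 82.5-fold lower (adjusted p = 0.0380). Mx2, an antiviral GTPase, had 13.2 ± 4.94 CPM in SDLN and 1 count in all over the skin libraries, a ratio of 649.8 with a 95% counting interval of 116 to 25712 (adjusted p = 0.0380). Interferon-stimulated genes that fell numbered 0 without any 1 SDLN library and 8 without skin 1. Fewer genes were detected in skin, 10858.5 against 13583. NF-kappaB target genes were higher as a group with the preset correlation (camera adjusted p = 5.44e-09) but did not pass with an estimated one (adjusted p = 0.0766 with an estimated correlation). Of 17 measured NF-kappaB targets, 7 rose, 0 fell and 10 did not pass, with 11 higher and 0 lower adjusted over the list alone. NF-kappaB targets that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. Tnfaip3, the NF-kappaB inhibitor A20, was at 55.8 ± 16.4 against 1492.5 ± 414 CPM (log2 fold change 4.74, adjusted p = 0.00162). Nfkbiz, an atypical inhibitor of the family, was at 82.7 ± 10.6 against 526 ± 103 CPM (log2 fold change 2.67, adjusted p = 0.00377). NF-kappaB targets that rose numbered 2 without any 1 SDLN library. Rtp4 and Oasl2 did not pass without any 1 SDLN library (adjusted p 0.0719 to 0.122, and 1.65e-18 to 0.156 over all alternatives). Nfkbiz did not pass with the replicate block (adjusted p = 0.0635, the highest over all alternatives). The sum of macrophage and dendritic cell markers, at 22.9 against 569 CPM, was higher in each skin library than in any SDLN library.

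Glycolysis and hypoxia genes were higher as a group with the preset correlation (camera adjusted p = 1.75e-07) but did not pass with an estimated one (adjusted p = 0.0766 with an estimated correlation). Of 21 measured glycolysis genes, 6 rose, 0 fell and 15 did not pass, with 7 higher and 0 lower adjusted over the list alone. Glycolysis genes that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. The glycolytic enzyme Tpi1 was at 57.5 ± 10.98 against 393 ± 99.0 CPM (log2 fold change 2.78, adjusted p = 0.00502), and Aldoa, another, at 813 ± 145 against 2655 ± 543 CPM (log2 fold change 1.71, adjusted p = 0.0129). Glycolysis genes that rose numbered 0, 0 and 1 without SDLN 1, 2 and 3. Macrophage and dendritic markers, at 22.9 against 569 CPM in sum, were higher alongside. In the cell cycle list, Mcm6, a subunit of the replicative helicase, rose, at 37.0 ± 3.998 against 155 ± 44.6 CPM (log2 fold change 2.07, adjusted p = 0.0200). Top2a, a topoisomerase, rose too, at 65.6 ± 5.48 against 178 ± 46.6 CPM (log2 fold change 1.44, adjusted p = 0.0380). Of 30 measured cell cycle genes, 2 rose, 0 fell and 28 did not pass, with 2 higher and 0 lower adjusted over the list alone. Cell cycle genes that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. For cell cycle genes the camera adjusted p was 0.315, and adjusted p = 0.689 with an estimated correlation. Cell cycle genes that rose numbered 0 without any 1 SDLN library and 1 without skin 4. Cell cycle genes that fell numbered 1 without skin 4. Cell cycle genes passed the list test without skin 2 (adjusted p = 0.0235, and 0.0235 to 0.987 over all alternatives). Tpi1 did not pass without SDLN 1 or SDLN 2 (adjusted p 0.0519 to 0.0552, and 9.71e-17 to 0.0635 over all alternatives). Aldoa and Mcm6 did not pass without any 1 SDLN library (adjusted p 0.0638 to 0.159, and 5.48e-09 to 0.198 over all alternatives). Top2a did not pass without any 1 SDLN library or without skin 4 (adjusted p 0.0547 to 0.191, and 1.74e-04 to 0.356 over all alternatives).

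Oxidative phosphorylation genes did not pass the test one by one or as a group with camera, but as a group passed downward with fry (adjusted p = 0.0415). Of 26 measured oxidative phosphorylation genes, 0 rose, 0 fell and 26 did not pass, with 0 higher and 0 lower adjusted over the list alone. Oxidative phosphorylation genes that were higher numbered 0 in edgeR, 1 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom. Oxidative phosphorylation genes that were lower numbered 0 in edgeR, 5 at an unadjusted p under 0.05, 3 with DESeq2 and 1 with limma-voom. For oxidative phosphorylation genes the camera adjusted p was 0.380, and adjusted p = 0.651 with an estimated correlation. Atp5a1, a subunit of ATP synthase and the most abundant member, was at 1037 ± 69.8 against 563 ± 245 CPM (log2 fold change -0.88, adjusted p = 0.212). Without skin 3 it passed (log2 fold change -1.17, adjusted p = 0.0470, the lowest over all alternatives). Oxidative phosphorylation genes that fell numbered 1 without skin 1 and 2 without skin 3. Cholesterol synthesis and uptake genes did not pass one by one or as a group with camera. Of 20 measured cholesterol genes, 0 rose, 0 fell and 20 did not pass, with 0 higher and 0 lower adjusted over the list alone. Cholesterol genes that were higher numbered 0 in edgeR, 3 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom. Cholesterol genes that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. For cholesterol genes the camera adjusted p was 0.0832, and adjusted p = 0.516 with an estimated correlation. Sc5d, an enzyme of late cholesterol synthesis and the most abundant member, was at 265 ± 16.5 against 205 ± 172 CPM (log2 fold change -0.37, adjusted p = 0.872). Cholesterol genes that rose numbered 2 without skin 1 and 1 without skin 2. Cholesterol genes that fell numbered 1 without skin 2. Cholesterol genes passed the list test without skin 2 or skin 4 (adjusted p = 0.0399 and 0.0164, and 0.0164 to 0.551 over all alternatives). Cytosolic ribosomal protein genes were lower as a group with the preset correlation (camera adjusted p = 4.04e-04) but did not pass with an estimated one (adjusted p = 0.516 with an estimated correlation). Of 34 measured ribosomal protein genes, 0 rose, 3 fell and 31 did not pass, with 0 higher and 6 lower adjusted over the list alone. Ribosomal protein genes that were higher numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. The list did not pass with limma-voom with sample weights or with group weights either (adjusted p = 0.0746 and 0.0542). Rpl4 was at 3546 ± 627 against 1486.5 ± 339 CPM (log2 fold change -1.25, adjusted p = 0.0362), Rpl8 at 2070.3 ± 482 against 853 ± 223 CPM (log2 fold change -1.28, adjusted p = 0.0380) and Rps18 at 200.1 ± 70.3 against 59.8 ± 23.0 CPM (log2 fold change -1.74, adjusted p = 0.0393). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain where reads align to several places. Ribosomal protein genes that fell numbered 0 without any 1 SDLN library, 1 without skin 2 and 6 without skin 4. Genes detected in skin were fewer, 10858.5 against 13583. Rpl4 did not pass without any 1 SDLN library (adjusted p 0.108 to 0.167, and 7.14e-05 to 0.221 over all alternatives). Rpl8 did not pass without any 1 SDLN library or without skin 2 (adjusted p 0.0640 to 0.167, and 3.56e-04 to 0.179 over all alternatives).

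Immediate early genes, which are induced within minutes of stimulation and also by tissue dissociation, were higher as a group with the preset correlation (camera adjusted p = 1.06e-12) but did not pass with an estimated one (adjusted p = 0.0605 with an estimated correlation). Of 21 measured immediate early genes, 9 rose, 0 fell and 12 did not pass, with 15 higher and 0 lower adjusted over the list alone. Immediate early genes that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. Fos was among them, and Nr4a1, a nuclear receptor induced by T cell receptor signals, was at 101 ± 2.89 against 2064 ± 613 CPM (log2 fold change 4.35, adjusted p = 0.00127). Immediate early genes that rose numbered 4, 3 and 5 without SDLN 1, 2 and 3. Heat shock genes were higher as a group with the preset correlation (camera adjusted p = 2.46e-04) but did not pass with an estimated one (adjusted p = 0.118 with an estimated correlation). Of 13 measured heat shock genes, 3 rose, 0 fell and 10 did not pass, with 5 higher and 0 lower adjusted over the list alone. Heat shock genes that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. The members past the test were Hspa1a, Hspa1b and Hsp90aa1. Hsp90aa1, an inducible HSP90 chaperone, was at 22.2 ± 3.98 against 152 ± 85.0 CPM (log2 fold change 2.77, adjusted p = 0.0374). Hspa1b, an inducible HSP70 chaperone, had 1 count in all over the SDLN libraries and 45.9 ± 34.0 CPM in skin. The ratio of Hspa1b was 2054, with a 95% counting interval of 368 to 81177 (adjusted p = 0.0195). Hspa1a had no SDLN count and 44.2 ± 38.3 CPM in skin, at least 207-fold higher (adjusted p = 0.0380). Hspa1a and Hspa1b are near-identical copies, and the division of reads between them is uncertain. Heat shock genes that rose numbered 0 without any 1 SDLN library. Hspa1b and Hsp90aa1 did not pass without any 1 SDLN library (adjusted p 0.117 to 0.176, and 6.22e-10 to 0.277 over all alternatives). Alongside both lists, macrophage and dendritic markers were higher, at 22.9 against 569 CPM in sum. Skin 4 had the highest sum of macrophage and dendritic markers, at 1316 CPM, and skin 3 the highest of keratinocyte and fibroblast markers, at 1746 CPM and 3151 CPM.

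**Figure D3:**
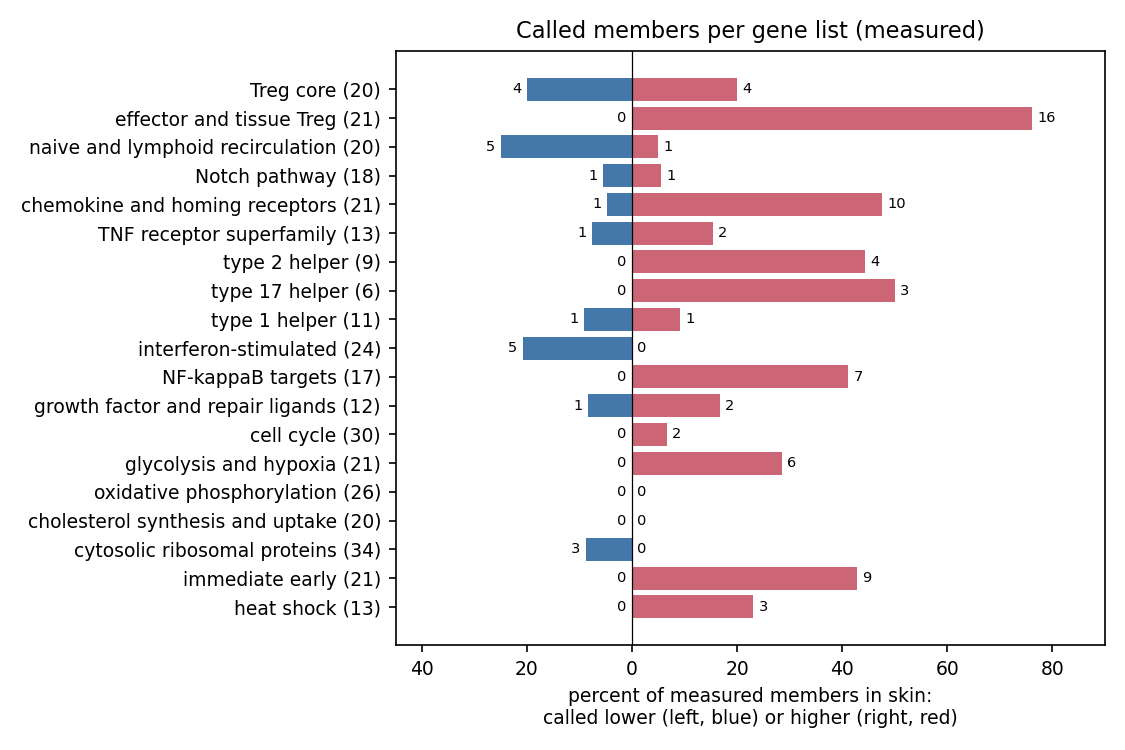
Share of the measured members of each gene list (y axis, number measured in parentheses) that passed an adjusted p of 0.05 over all genes, lower in skin to the left and higher to the right (x axis, percent; numbers at the bars count the members). Effector and tissue Treg genes have 16 of 21 members higher, and oxidative phosphorylation and cholesterol genes have 0 of 26 and 0 of 20 past the test.

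Markers of other cell types varied between the skin libraries. Macrophage, dendritic and Langerhans cell markers were higher as a group with the preset correlation (camera adjusted p = 2.10e-07) but did not pass with an estimated one (adjusted p = 0.0835 with an estimated correlation). Of 10 measured myeloid markers, 4 rose, 0 fell and 6 did not pass, with 7 higher and 0 lower adjusted over the list alone. Myeloid markers that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. Those past the test were Lyz2, Epcam (log2 fold change 3.60, adjusted p = 0.0380), Cd209a (log2 fold change 9.12, adjusted p = 0.0385) and Mgl2. Mgl2, a lectin, had 1 count in all over the SDLN libraries, a ratio of 4742 with a 95% counting interval of 851 to 187340.0 (adjusted p = 0.0114). Lyz2, the myeloid lysozyme, was at 11.6 ± 3.65 against 194 ± 191 CPM (log2 fold change 4.06, adjusted p = 0.0380). The list summed to 1316 CPM in skin 4 and 287 to 341 CPM in the other skin libraries. Myeloid markers that rose numbered 0 without any 1 SDLN library and 2 without skin 4. Lyz2 did not pass without any 1 SDLN library (adjusted p 0.165 to 0.176, and 1.67e-06 to 0.267 over all alternatives). Its log2 fold change was 3.13 without skin 4. In skin 3, keratinocyte markers summed to 1746 CPM, against 30.6 to 46.4 CPM in the other skin libraries. Hair follicle markers there summed to 1582 CPM against 0 to 2.71 CPM, and fibroblast markers to 3151 CPM against 3.35 to 11.7 CPM. The most abundant members were the keratins Krt17 and Krt71 and the collagen Col3a1, at 542, 689.5 and 1453 CPM in skin 3. In the other skin libraries they were at most at 0, 0.0713 and 1.78 CPM. Krt17 and Krt71 did not pass the low-count filter, and Col3a1 had no SDLN count and did not pass the test (adjusted p = 0.219). Krt10, a keratin, fell, with 2.54 ± 0.115 CPM in SDLN and 1 count in all over the skin libraries, a ratio of 123.3 with a 95% counting interval of 21.7 to 4914 (adjusted p = 0.0380). Of 4 measured keratinocyte markers, 0 rose, 1 fell and 3 did not pass, with 1 higher and 1 lower adjusted over the list alone. Keratinocyte markers that were higher numbered 0 in edgeR, 1 at an unadjusted p under 0.05, 1 with DESeq2 and 1 with limma-voom. Lower ones numbered 1 in edgeR, 1 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma-voom. For keratinocyte markers the camera adjusted p was 0.493, and adjusted p = 0.689 with an estimated correlation. The camera direction of the keratinocyte list was up and that of fry down. Keratinocyte markers that rose numbered 1 without skin 1 and 1 without skin 3. Keratinocyte markers that fell numbered 0 without any 1 SDLN library. Of 5 measured fibroblast markers, 0 rose, 0 fell and 5 did not pass, with 2 higher and 0 lower adjusted over the list alone. Fibroblast markers that were higher numbered 0 in edgeR, 4 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma-voom. Fibroblast markers that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. For fibroblast markers the camera adjusted p was 0.0568, and adjusted p = 0.516 with an estimated correlation. The fibroblast list had a median log2 fold change of 11.60, or 7.22 with members at 0 in SDLN at their bound. That median was 9.85, 10.3 and 9.65 without SDLN 1, 2 and 3, and 6.44 to 11.9 over all alternatives. Fibroblast markers that rose numbered 1 without skin 3. Fibroblast markers passed the list test without SDLN 1, SDLN 2, SDLN 3 or skin 4 (adjusted p = 0.0303, 0.0384, 0.0431 and 0.0222, and 0.00482 to 0.516 over all alternatives). The 1 measured hair follicle marker did not pass, nor at an unadjusted p under 0.05, with DESeq2, with limma-voom or adjusted over the list alone, but it was lower without skin 3.

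B cell markers were lower as a group with the preset correlation (camera adjusted p = 9.45e-05) but did not pass with an estimated one (adjusted p = 0.0605 with an estimated correlation). Of 7 measured B cell markers, 0 rose, 2 fell and 5 did not pass, with 0 higher and 3 lower adjusted over the list alone. B cell markers that were higher numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. The list summed to 103 ± 11.8 CPM (SD, n = 3) in SDLN and 61.1 ± 68.8 CPM (SD, n = 4) in skin (exact permutation p = 0.314, adjusted 0.686). Skin 3 had 160.1 CPM, above the 94.3 to 116 CPM of the SDLN libraries, and the other skin libraries had 3.07 to 50.2 CPM. The median log2 fold change of the list was -3.84, and -3.23 without skin 1, -8.83 without skin 3 and -5.12 without skin 4. Fcer2a had no count in skin and was at least 17.8-fold lower (adjusted p = 0.0380). It passed the low-count filter through SDLN alone, and nearly all tested genes with no skin count were called. Cd79b, a chain of the B cell receptor and the most abundant member, was at 64.1 ± 12.05 against 17.5 ± 20.1 CPM (log2 fold change -1.87, adjusted p = 0.659). B cell markers that fell numbered 0 without any 1 SDLN library and 4 without skin 3. Pecam1, an adhesion molecule of endothelial and some lymphoid cells, fell, at 488 ± 87.4 against 40.8 ± 19.1 CPM (log2 fold change -3.58, adjusted p = 0.00856). The endothelial list summed to 492 ± 86.9 CPM (SD, n = 3) in SDLN and 50.2 ± 33.9 CPM (SD, n = 4) in skin (exact permutation p = 0.0286, adjusted 0.257). Pecam1 made up most of this sum in both tissues, so the sum does not show that other endothelial markers were lower. Of 2 measured endothelial markers, 0 rose, 1 fell and 1 did not pass, with 0 higher and 1 lower adjusted over the list alone. Endothelial markers that were higher numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. Endothelial markers that fell numbered 0, 0 and 1 without SDLN 1, 2 and 3. Pecam1 did not pass without SDLN 1 or SDLN 2 (adjusted p 0.0519 to 0.0525, and 1.76e-12 to 0.0763 over all alternatives). Nkg7, a cytotoxic granule protein, was at 102 ± 38.2 against 179 ± 58.2 CPM (log2 fold change 0.81, adjusted p = 0.339). Of 5 measured CD8 T and NK cell markers, 0 rose, 0 fell and 5 did not pass, with 0 higher and 0 lower adjusted over the list alone. CD8 T and NK cell markers that were higher numbered 0 in edgeR, 0 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom. CD8 T and NK cell markers that were lower numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. For CD8 T and NK cell markers the camera adjusted p was 0.671, and adjusted p = 0.689 with an estimated correlation. CD8 T and NK cell markers that fell numbered 1 without skin 4.

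Of 11 listed gamma-delta T cell markers, 3 were among the gene symbols of the data, so the list says little about these cells. Xcl1, a chemokine and the 1 measured gamma-delta T cell marker, had no skin count and was at least 7.09-fold lower (adjusted p = 0.0380). The list had 0 higher and 1 lower adjusted over the list alone. Counts lower were 1 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma-voom, and counts higher 0, 0 and 0. Xcl1 did not pass without any 1 SDLN library (adjusted p 0.165 to 0.176, and 0.00634 to 0.358 over all alternatives). Adipoq, the adipocyte hormone adiponectin, was at least 5.64-fold lower with no skin count (adjusted p = 0.0380). Of 3 measured muscle and adipocyte markers, 0 rose, 1 fell and 2 did not pass, with 0 higher and 1 lower adjusted over the list alone. Muscle and adipocyte markers that were higher numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. Lower ones numbered 1 in edgeR, 1 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma-voom. For muscle and adipocyte markers the camera adjusted p was 0.123, and adjusted p = 0.346 with an estimated correlation. Muscle and adipocyte markers that fell numbered 0 without any 1 SDLN library. Cpa3, a mast cell protease, was at least 6.73-fold lower with no skin count (adjusted p = 0.0380). Xcl1, Adipoq and Cpa3 passed the low-count filter through SDLN alone. Nearly all tested genes with no skin count were called (269 of 271), so these calls say little about the cell types. Of 3 measured mast cell markers, 0 rose, 1 fell and 2 did not pass, with 0 higher and 1 lower adjusted over the list alone. Mast cell markers that were higher numbered 0 in edgeR, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. Lower ones numbered 1 in edgeR, 1 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma-voom. For mast cell markers the camera adjusted p was 0.226, and adjusted p = 0.395 with an estimated correlation. Mast cell markers that fell numbered 0 without any 1 SDLN library. The mast cell list had a median log2 fold change of 0.05, a mean of -1.75 and a downward test. Mylpf, a muscle myosin light chain, was at 14.96 ± 1.70 against 6.05 ± 11.1 CPM and did not pass (adjusted p = 0.818). Kit, a growth factor receptor of mast cells, was at 8.66 ± 3.55 against 8.94 ± 12.3 CPM (adjusted p = 0.995). Pmel, a melanosome protein, was at 21.1 ± 2.33 against 6.10 ± 9.78 CPM (adjusted p = 0.728). Alas2, an enzyme of erythroid haem synthesis, was at 3.48 ± 0.158 against 6.28 ± 12.4 CPM (adjusted p = 0.917). The 2 measured melanocyte markers and the 1 measured erythroid marker did not pass, 0 also adjusted over each list alone, at an unadjusted p under 0.05, with DESeq2 and with limma-voom. No neutrophil marker passed the low-count filter, and S100a8 was at 7.93 CPM in skin 3 and at 0 in the other skin libraries.

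**Figure D4:**
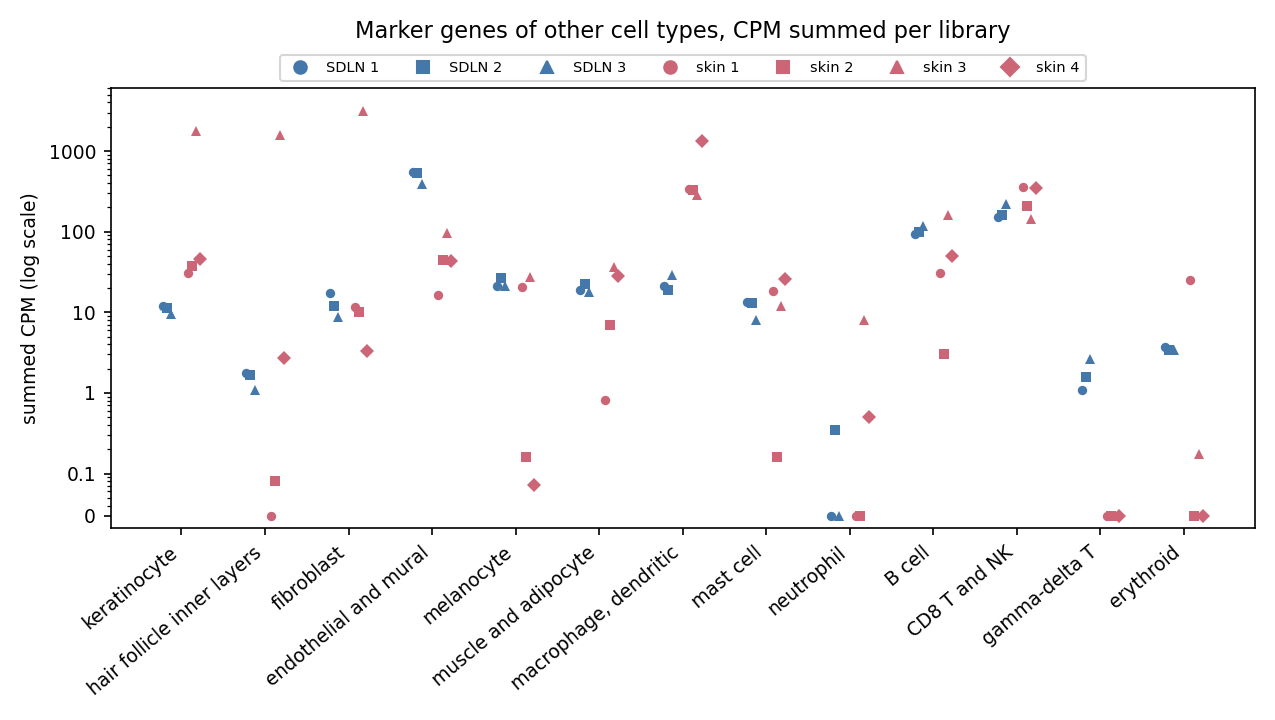
Summed CPM of the marker genes of other cell types (x axis) in each library (y axis, log scale, with 0 drawn at the bottom). Skin 3 stands apart for keratinocyte, hair follicle and fibroblast markers, at 1746 CPM, 1582 CPM and 3151 CPM, and skin 4 for macrophage and dendritic markers, at 1316 CPM.

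Over the 26 lists with at least 3 measured members, 14 passed the camera test with a preset correlation, 10 of them up and 4 down, and 1 passed with an estimated correlation. With limma's fry, which asks whether a list's own genes move on balance one way, 16 passed, and 24 passed when either direction counted.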

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

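None of the results in this part was tested further, and the values for which 1 skin library stood apart were found by a gap test (Dixon's test at 95%) fixed before the results were seen. Of 78 gene levels and library measures checked over the 4 skin libraries, 16 had such a library; 9 were in skin 3, 3 each in skin 1 and skin 4, and 1 in skin 2. These items overlap: the S100a8 and Alas2 values are also the neutrophil and erythroid sums of those libraries, and Krt17, Krt71 and Col3a1 are part of their lists' sums, so their number is not set against chance. Groups of 3, such as the SDLN libraries, were not checked.

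In skin 3, the keratins Krt17 and Krt71 had 542 CPM and 689.5 CPM, with at most 0 and 0.0713 in the other skin libraries, and the collagen Col3a1 had 1453 CPM, with 0.428 to 1.78. The summed keratinocyte markers reached 1746 CPM there against 30.6 to 46.4, hair follicle markers 1582 CPM against 0 to 2.71, and fibroblast markers 3151 CPM against 3.35 to 11.7. S100a8, a neutrophil protein, had 7.93 CPM in skin 3 and 0 in the others, and the neutrophil markers summed to 7.93 CPM against 0 to 0.499. The ribosomal RNA precursor Rn45s took 1.37% of the gene counts of skin 3 and 0.147% to 0.344% of the others. In skin 4, macrophage, dendritic and Langerhans cell markers summed to 1316 CPM against 287 to 341, the muscle gene Mylpf had 22.6 CPM against 0 to 1.32, and Stat4 had 89.6 CPM against 23.8 to 34.9. In skin 1, S1pr1 had 119 CPM against 45.2 to 54.8, and Alas2, the sole erythroid marker with a count there, had 24.9 CPM against 0 to 0.176, which was also the erythroid sum. In skin 2, Lmna had 1429.6 CPM against 459.7 to 623.

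Reads outside annotated genes, which no comparison used, made up 43.1 ± 3.45% (SD, n = 4) of the reads counted to a gene or to none in skin and 35.3 ± 1.84% (SD, n = 3) in SDLN (exact permutation test, two-sided, p = 0.0571). The lowest skin share, 38.1% in skin 1, was above the highest SDLN share, 37.4% in SDLN 2.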

How the results depend on the processing

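Of these settings, the weight per group and the sex covariate were chosen after seeing the data. No called gene changed sign where a setting tested it, and of 46 named genes called, 15 stayed called in the 20 settings run for single genes, which leave out the adjusted p under 0.01 and the fold of 1.5 (among them Rora, Ahnak, N4bp1, Lmna, Fosl2, Gem, Myadm, Gpr18, Gimap4, S1pr1, Ift80, Il1rl1, Tnfaip3 and Nr4a1). Counts of genes were within 1.5 times of 373 higher and 451 lower under RLE, upper-quartile and no scaling, without robust fitting and against a fold of 1.5. Higher and lower genes numbered 188 and 70 without the filter (16157 genes tested) and 285 and 99 at a mean of at least 5 CPM (9976 tested). With DESeq2 they were 923 and 507. DESeq2 called all 373 of the higher genes but 263 of the 451 lower ones, and gave no adjusted p for 719 genes. Higher and lower genes were 247 and 688 with limma-voom, 763 and 1024 with sample weights, and 72 and 16 at an adjusted p under 0.01, a stricter threshold. Apart from that threshold, the cause of these differences was not tested. The counts were 593 and 1002 with a weight per group, a method of whose calls 89.2% were false in simulated data with a spread per tissue. With sex as covariate they were 62 and 16, but SDLN 3 was the sole male library. The sex term therefore fits SDLN 3 exactly and acts much as leaving it out, which gave 61 and 15. With the replicate block they were 32 and 10 on 6 libraries, where the same 6 without the block gave 311 and 590, and 44 and 12 on 7. The block also removes degrees of freedom. After removing tissue means, equal numbers correlated at 0.0672, -0.0018 and -0.0401, and unequal numbers at -0.0793 to 0.102. Such values neither show nor exclude that numbers 1 and 2 pair libraries. Number 3 did not mark the same animals, since Ddx3y had 3877 counts in SDLN 3 and 2 in skin 3. Without 1 library, with fewer samples, they ranged from 33 to 582 and from 9 to 822. Lists past the camera test ranged from 11 to 17 around 14, and 1 was left with an estimated correlation. Upper-quartile scaling moved the median log2 fold change of all genes by -0.10, the limma-voom settings by about -0.39 and the block by about -0.40.

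Uncalled results that turned direction, cause not tested, were these in log2 fold change. Kit (0.05) was at -0.0051 without the filter, -2.79 with limma-voom, -1.44 with sample weights, -2.77 with group weights, -5.20 and -5.16 with the replicate block, -0.26 with sex, and -1.49 to 0.46 without 1 library. Alas2 (0.85) was at -3.46, -4.34 and -3.50 with limma-voom, sample weights and group weights, -3.55 and -3.51 with the block, and -5.73 to 1.26 without 1 library. Medians of lists whose test turned were -0.51 (Notch) and 0.66 (CD8 T and NK) at a mean of at least 5 CPM, -0.50 and -0.47 (cell cycle) and -1.86 and -0.62 (CD8 T and NK) with the block, and -0.76 to 1.02 (CD8 T and NK) without 1 library. The type 2 list, called upward, turned downward in its test without shared members, at a median of 0.69 (adjusted p = 0.915), cause not tested. At 3 counts, depth allows no level under 0.204 to 0.276 CPM to be told from 0.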

Other observations

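The families and tests in this part were chosen after the results were seen, except the thinning of the genes with no skin count and the list tests of heat shock, B cell and macrophage and dendritic genes. List tests of the families were adjusted over these families alone. As the families were picked from the same values, these list tests lend them no support. Among genes of the circadian clock, Per1, Arntl, Nr1d1, Nr1d2 and Per3 rose in skin Tregs and 8 of 13 measured members did not pass (camera adjusted p = 4.55e-04, and adjusted p = 0.0491 with an estimated correlation). Per1, a repressor of the clock's feedback loop, was at 7.72 ± 0.933 against 149.9 ± 38.7 CPM (log2 fold change 4.28, adjusted p = 0.00369), and Arntl, the activator BMAL1, at 17.8 ± 2.58 against 88.4 ± 30.7 CPM (log2 fold change 2.31, adjusted p = 0.0380). Among dual-specificity phosphatases, several of which switch off MAP kinases, Dusp1, Dusp14, Dusp4, Dusp3 and Dusp5 rose and 11 of 16 did not pass (camera adjusted p = 9.85e-05, and adjusted p = 0.0491 with an estimated correlation). Dusp1, also an immediate early gene, was at 6.37 ± 2.04 against 1142 ± 830.2 CPM (log2 fold change 7.48, adjusted p = 0.00388). Anxa1 and Anxa2 rose among 8 annexins, which bind membranes in the presence of calcium (camera adjusted p = 0.00165, and adjusted p = 0.0516 with an estimated correlation), with Anxa1 at 8.79 ± 1.37 against 351 ± 179.6 CPM (log2 fold change 5.32, adjusted p = 0.00388), and S100a4, S100a6 and S100a11 rose among 7 calcium-binding S100 genes (camera adjusted p = 9.85e-05, and adjusted p = 0.127 with an estimated correlation), with S100a4 at 30.8 ± 13.6 against 569 ± 295 CPM (log2 fold change 4.21, adjusted p = 0.00998). Gimap4, Gimap3, Gimap9 and Gimap6 fell among 8 GTPases of the Gimap family (camera adjusted p = 1.20e-04, and adjusted p = 0.0892 with an estimated correlation), with Gimap3 at 2095 ± 55.5 against 215 ± 117 CPM (log2 fold change -3.28, adjusted p = 0.0116); these are close paralogs, and the split of reads between them is uncertain. Cct5, Cct3 and Tcp1 fell among 8 subunits of the chaperonin that folds actin and tubulin (camera adjusted p = 0.0166, and adjusted p = 0.231 with an estimated correlation), and Psmb8, an immunoproteasome subunit, among 37 proteasome genes (camera adjusted p = 0.0166, and adjusted p = 0.319 with an estimated correlation). These families were not tested with 1 library left out. Macrophage and dendritic markers, at 22.9 against 569 CPM in sum, were higher alongside the families that rose. Genes detected were fewer in skin, at 10858.5 against 13583, alongside those that fell.

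A first pattern is that 269 of the 451 genes called lower had no count in any skin library. Lower total counts alone are argued against: at their SDLN shares and the lowest skin total of 11009600 the 269 genes would have had a median of 31.2 counts and at least 9.95, where each had 0 in all 4 skin libraries. Over the whole table with no filter, 10072 genes had no count in the 4 skin libraries, against 9370 in the 3 SDLN libraries thinned to that total; each of these kept at least 13249 genes with a count, and skin libraries had at most 12639. That 0% of the 269 genes had 0 counts in any thinned SDLN library adds nothing, since these genes, kept by the low-count filter, had at least 11 counts in each SDLN library. Independent loss in each skin library at rates shared by genes of like abundance, length and GC content is argued against too, since 264 matched genes were at 0 in all 4 skin libraries where such rates give 58.8, a ratio of 4.49. Of these, 198 had under 5 CPM in SDLN (55.6 given by such rates), 56 had 5 to 20 (3.16) and 10 had 20 or more (0.0894). Loss before amplification that strikes the same genes in each skin library, and lower expression in skin Tregs, may both apply and stay open.

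A further pattern is the rise of immediate early genes in skin. RNA of keratinocytes, fibroblasts or hair follicle cells is argued against as the source, since 9 members were higher without skin 3, which held most of those cells' markers, as with all libraries. A response to taking cells out of the tissue cannot be told apart from a difference between Tregs in place, because every skin library and no SDLN library came from skin; the heat shock list, which such a response could raise, had a median log2 fold change of 1.14 and passed with the preset but not with an estimated correlation (adjusted p = 2.46e-04 and 0.118). RNA of myeloid cells was not tested for these genes and stays open.

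The last pattern is that H2-Ab1, H2-Aa and H2-Eb1, which present antigen on MHC class II, rose while 7 of 10 measured members of the family did not pass (camera adjusted p = 0.0352, and adjusted p = 0.405 with an estimated correlation), with H2-Ab1 at 9.18 ± 4.82 against 334 ± 257 CPM (log2 fold change 5.18, adjusted p = 0.0347). RNA of B cells is argued against in skin 1, 2 and 4, where B cell markers summed to 31.0, 3.07 and 50.2 CPM, under the 94.3 to 116 CPM of the SDLN libraries, while Cd74, H2-Aa, H2-Ab1 and H2-Eb1 summed to 3234, 2900 and 11187 CPM against 334 to 542 CPM. The B cell list passed downward with a median log2 fold change of -3.84 (-3.23 without skin 1, -8.83 without skin 3 and -5.12 without skin 4), but not with an estimated correlation (adjusted p = 0.0605). In skin 3, with 160 CPM of B cell markers and 617 CPM of those 4 genes, RNA of B cells stays open. RNA of macrophages or dendritic cells may contribute: their list passed upward with the preset but not with an estimated correlation (adjusted p = 2.10e-07 and 0.0835), with 4 members called, and 0 called without any 1 SDLN library. Its most abundant member, Lyz2, was at 11.6 ± 3.65 against 194 ± 191 CPM, and the excess of MHC class II over that of myeloid markers was 8.85, 8.01 and 8.33 in skin 1, 2 and 4. In skin 3 it was 0.741, an 11.9-fold spread that passed the bound of 10 set for arguing against this source, but it rests on 1 library and the bound was set aside for that reason after the value was seen, so myeloid RNA and expression by Tregs cannot be told apart. A sort gate on the Foxp3 reporter would remove such cells, but the gates are not given in the sources used here.

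Other splits of the 7 libraries into 3 and 4 were tested for each count. Of the 35 splits, 1, the real one, gave as many as 373 higher genes and 1 as many as 451 lower, where the highest of the others gave 1 and 0. That share of splits, 0.0286, is under 0.05 but is the smallest that 35 splits allow. Every other split also puts SDLN and skin libraries in the same group, which widens the spread within it. Few calls in those splits therefore do not exclude chance for either count. For the 14 lists past the camera test chance cannot be excluded, since 4 of the 35 splits gave as many and the highest other gave 18; the splits that set 3 skin libraries apart, which move 1 skin library to the SDLN side, gave 13 to 18 and all others at most 12. At an unadjusted p under 0.05 the real split gave 2111 genes and the highest other 1873.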
